A study of Mus musculus with 12 samples.

How the data were processed

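RNA was sequenced from mouse oocytes collected 0.5 days after mating with vasectomized males, from females that had eaten a high-fat diet (HFD) or a control diet (CD) for 9 weeks. The labels name both diets by the same product code, the HFD as a modified form of it, so what the control feed contained is uncertain. Groups and directions follow the labels' diet names. Each library was made from a pool of 4 oocytes, and each diet had 6 libraries, which the labels number 1 to 6. The labels give 6 females per diet but do not state which female gave which pool, so the p-values measure the spread between these pools, part of which may be technical. Per the labels' protocols, full-length cDNA was made by template switching with the SMART-Seq v4 kit, purified on beads, and turned into libraries by tagmentation with Nextera XT. This chemistry does not mark the strand.

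The deposited table held whole-number read counts per gene symbol, not normalised, for 24062 genes in 12 libraries, with 5 further lines holding the counter's own tallies of unassigned reads. Per the submitters' processing notes, the sources name STAR, HTSeq 1.0.0, DESeq2 1.0.19 and the genome build mm10. The version of STAR, the annotation and the counting options are not given in the sources used here. The counter's tallies were kept out of library sizes and gene tests. They made up 66.5% to 72.9% of all tallied reads in the HFD libraries and 62.3% to 66.6% in the CD libraries, most of them reads overlapping no annotated gene or aligned to more than 1 place. Every count in 4 of the 6 HFD libraries (replicates 1, 2, 4 and 6) was even. In the other 8 libraries, 50.8% to 52.1% of the counts above 0 were odd. All-even counts point to doubled tallies in those 4 HFD libraries. The counts were used as deposited, and halving the all-even libraries was an alternative.

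Gene counts summed to between 8409491 and 13793598 per HFD library and between 8556396 and 10477316 per CD library. Counts of libraries of the same diet differed by far more than sampling noise, with 27.7 to 295 chi-square units per degree of freedom over the pairs, so no library is a copy of another of its diet. This cannot exclude repeat preparations of 1 pool, and the libraries were counted as separate pools because the labels list them so. Reads carried no molecular identifiers, so a count is not a number of independent molecules. Gene symbols were matched to GENCODE mouse release M21, which uses the same build as the counts. Of the symbols, 23685 matched and 377 did not. Coordinates, transcript lengths and GC contents came from that annotation, and 99.2% of the tested genes had a length.

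The comparison of HFD with CD used edgeR 4.0.16 under R 4.3.3, with TMM normalisation, the default filter on low counts, and the robust quasi-likelihood F-test with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over the 9935 genes that passed the filter, with a threshold of 0.05. In all, 6927 genes had no count in any library. Log2 fold changes are HFD minus CD. Their standard errors (SE) were derived from the fold change and its F statistic. Expression levels are CPM, gene counts scaled to a common library total with the TMM factors, given as mean ± SD with n = 6 per diet, unless they are named as CPM of total gene counts. Values on the log2 scale used a prior count of 2.

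For 28 lists of genes fixed beforehand, camera in limma 3.58.1 asked whether the members moved relative to the other genes, with a preset correlation of 0.01 and adjustment over the 26 lists with at least 5 tested members. Camera with a correlation estimated per list, and fry, were alternatives. The mitochondrially encoded list had no symbol in the table as used here, and the blood and immune list had too few tested members. A list score per library was the mean over members of log2 CPM minus the mean of the CD libraries, compared by a two-sided exact permutation test over all assignments of 6 of the 12 libraries. The smallest p that this test can give is 0.00216. The same exact test was used for 5 library measures (total counts, genes detected, genes detected after thinning all libraries to the smallest total, the share of counts in the 50 highest genes, and the summed CPM of cumulus and granulosa markers), for each library's distance from the other libraries of its diet, and for the counter's tallies.

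Genes named in the text followed a rule. It took genes past the threshold, or, as fewer than 10 passed, the 10 smallest p in each direction, then up to 2 members with the smallest p of each list without a passing member, and Zp3, Gdf9 and Bmp15 as oocyte identity controls. Any other gene is named as chosen after its values were seen. Ribosomal protein genes have processed pseudogenes that can share their reads, and Znrd1as and Airn overlap genes on the other strand, so their counts are uncertain.

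Alternatives chosen beforehand were DESeq2's size factors, total counts alone, no filter on low counts, a mean of at least 10 CPM, the replicate number as a block, the number of detected genes as a covariate, a fit that was not robust, an adjusted p of 0.10, DESeq2 1.42.0, limma-voom with quality weights, and leaving out each library in turn. Added after the counts were seen were halved counts in the all-even libraries, the 8 libraries with odd counts only, 1 or 2 surrogate variables (sva 3.50.0), corrections for transcript length and for GC content by offsets per library (loess span 0.5), the length correction with the block, the length correction without HFD replicate 3, and the marker sum without Serpine2. The share of mitochondrially encoded counts and the normalisation without those genes were not run, as no such symbol was found in the table as used here. On counts simulated with these means and depths, edgeR called 8.96% of the genes changed 2-fold, 50.7% of those changed 4-fold and 74.2% of those changed 8-fold, and 2 of 9685 unchanged genes. DESeq2 called 14.9%, 74.6% and 90.9%, and 18 unchanged genes. Each gene was simulated independently and at the deposited depths. Both the recovery of changed genes and the calls of unchanged genes therefore leave out any structure that genes share across libraries. Other groupings of the libraries were refitted for 100 splits with edgeR and for 24 with DESeq2 on the filtered genes, and DESeq2 was later refitted on the same 100 splits as edgeR.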

Results

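The transcriptomes of oocytes from 12 pools, 6 from females on the high-fat diet (HFD) and 6 from females on the control diet (CD), were compared to ask how the diet before mating altered the messenger RNA that an oocyte carries. The females had been mated with vasectomized males, and the oocytes were collected 0.5 days later. As deposited, gene counts summed to between 8409491 and 13793598 per HFD library and between 8556396 and 10477316 per CD library, with n = 6 per diet. Of 24062 genes, 12229 to 14755 were detected in the HFD libraries and 12344 to 13052 in the CD libraries.

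The oocyte identity genes Gdf9 and Bmp15 were abundant in both diets. Gdf9, an oocyte growth factor (chromosome 11, 53431023 to 53437904, mm10), stood at 4282 ± 3408 CPM in HFD and 4692 ± 3368 CPM in CD, a log2 fold change of −0.13 ± 0.75 (SE), which for gene Gdf9 ranged from −0.55 to 0.098 with each library left out. Bmp15, its partner of the same family (chromosome X, 6314107 to 6320721), stood at 621 ± 325 and 812 ± 528 CPM, a log2 fold change of −0.39 ± 0.42, or 0.025 for gene Bmp15 without CD replicate 3. Neither differed by more than the spread between pools (edgeR, adjusted p = 0.935 and 0.622). Zp3, a zona pellucida protein (chromosome 5, 135980099 to 135988624), had a log2 fold change of 3.65 ± 1.25 (edgeR, adjusted p = 0.121), and 4 of 6 HFD libraries lay above the CD mean. That value rested on HFD replicate 3, which held 4704 CPM of total gene counts, against 10.3 to 200 in the other 11 libraries, and without it the log2 fold change was 0.90.

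**Figure D1:**
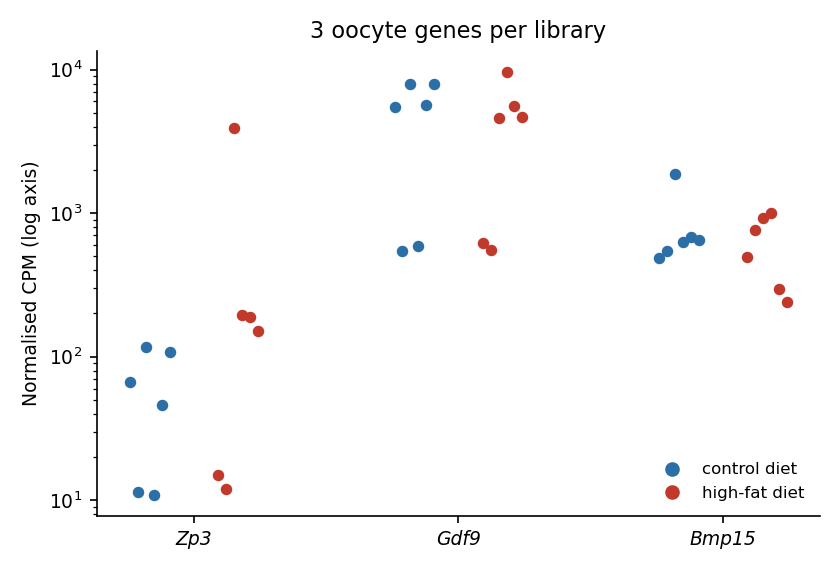
Levels of the oocyte identity genes Zp3, Gdf9 and Bmp15 in TMM-scaled CPM on a log axis, with 1 point per library, CD in blue and HFD in red. HFD replicate 3 stands above the others for Zp3 at 3942 CPM, while Gdf9 has low and high libraries in both diets.

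No single gene passed the threshold in the comparison of the diets. Among the 9935 genes tested with edgeR, the smallest adjusted p was 0.0913, shared by 224 genes, while 2215 genes had an unadjusted p under 0.05, of which 1332 were higher and 883 lower in HFD. At an adjusted p of 0.10, 470 genes would pass (340 higher and 130 lower). DESeq2 called 709 genes (474 higher and 235 lower), of which 676 had an unadjusted edgeR p under 0.05, and limma-voom with quality weights called 35. The biological coefficient of variation between pools was 64.0%. The values of the 6 HFD and 6 CD libraries did not overlap for 243 genes, 2.45% of those tested, where chance gives 0.216%.

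The genes with the smallest p-values lay on 1 side of the CD mean in every HFD pool, which their choice by p from these same libraries favours. Timm8b, a small chaperone of the mitochondrial intermembrane space (chromosome 9, 50603910 to 50605320), stood at 449 ± 117 CPM in HFD and 151 ± 49.7 CPM in CD, a log2 fold change of 1.57 ± 0.29. Ndufb8, a subunit of respiratory complex I (chromosome 19, 44548572 to 44555440), stood at 169 ± 90.4 and 44.1 ± 12.9 CPM, a log2 fold change of 1.94 ± 0.37. The ribosomal stalk protein gene Rplp2 (chromosome 7, 141447370 to 141451585) had a log2 fold change of 1.66 ± 0.33 and Rpl37 of 1.78 ± 0.37. The remaining 6 of the 10 were Lsm7 (1.95) and Nop10 (1.75), which encode parts of RNA-binding complexes, Myeov2 (1.57), Sergef (1.80), Ccdc122 (1.47) and Znrd1as (2.18, whose reads cannot be told from those of the gene on the other strand). Each of the 10 was above the CD mean in 6 of 6 HFD libraries, and none passed edgeR's adjustment (adjusted p = 0.0913 for each).

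Among the 10 genes with the smallest p that were lower in HFD, Ung, the uracil-DNA glycosylase of base excision repair (chromosome 5, 114130386 to 114139323), stood at 21.9 ± 9.85 CPM in HFD and 83.1 ± 20.1 CPM in CD, a log2 fold change of −1.92 ± 0.34. E2f4, a cell-cycle transcription factor (chromosome 8, 105297663 to 105305370), had a log2 fold change of −1.49 ± 0.31. Ube2s, a ubiquitin-conjugating enzyme that works with the anaphase-promoting complex, had −1.11 ± 0.25, and Ncoa4, a receptor for the autophagy of ferritin, −1.64 ± 0.39. The other 6 were Sh2d3c (−2.08), Naa40 (−1.40), Trim75 (−1.82), 4930512B01Rik (−2.54), Snx9 (−1.43) and Pla2g15 (−1.35). All 10 lay below the CD mean in 6 of 6 HFD libraries, again without passing edgeR's adjustment (adjusted p = 0.0913 for each). CD replicate 3 was the highest CD library for each of them except Ung and Ube2s, and so raised their CD means. For Sh2d3c it held 271 CPM, against 39.9 to 97.8 CPM in the other CD libraries. The values of the diets overlapped only for Trim75 and Ncoa4.

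**Figure D2:**
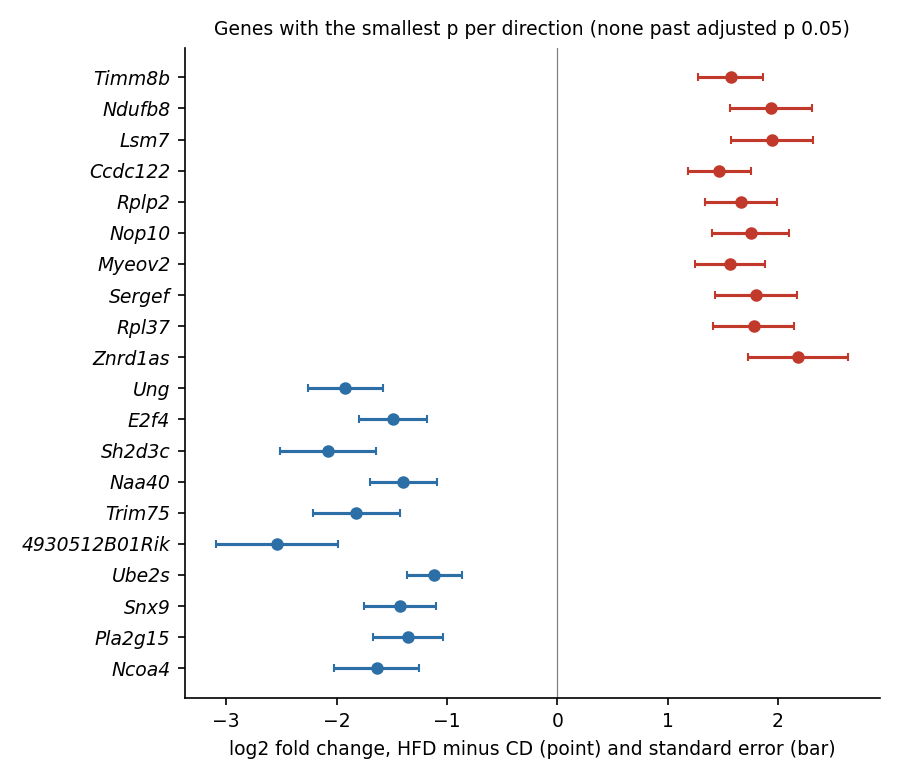
Log2 fold change, HFD minus CD, of the 10 genes with the smallest p in each direction, with bars for the SE (n = 6 per diet). The values run from −2.54 for 4930512B01Rik to 2.18 for Znrd1as, and none passed edgeR's adjustment.

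Gene lists asked whether processes fixed beforehand moved together, and 4 of the 26 lists tested passed camera's threshold at the preset correlation of 0.01. As many lists also passed in 34 of 100 splits of the libraries into 6 and 6, the real one included, with a median of 3 in the others. Estimated correlations between members ran from 0.06 to 0.65 in the 4 lists, above the preset, so camera's small p-values overstate the evidence. Nuclear-encoded subunits of oxidative phosphorylation (OXPHOS) were higher in HFD, with 64 of 68 tested members above 0 and 4 below, and a median log2 fold change of 2.22 (camera, adjusted p = 1.21e-18; adjusted p = 0.611 with an estimated correlation). Adjusted over the list alone, 55 members were higher and 2 lower by edgeR. Over all genes tested none passed with edgeR, while DESeq2 called 24 higher and 1 lower. Beside Ndufb8, the member with the smallest p was Cycs, cytochrome c, at 146 ± 95.3 CPM in HFD and 43.1 ± 12.8 CPM in CD, a log2 fold change of 1.76 ± 0.38. The 2 lower members, named here after their values were seen, were the large catalytic subunits Ndufs1 (−1.23) and Sdha (−0.66). The list score of every HFD library lay above all 6 CD libraries, a difference of 1.498 (exact permutation test, p = 0.00216; adjusted over the 26 lists, 0.0563).

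Cytoplasmic ribosomal protein genes were likewise higher in HFD, with all 54 tested members above 0 and a median log2 fold change of 1.94 (camera, adjusted p = 9.08e-17; adjusted p = 0.611 with an estimated correlation). Adjusted over the list alone, 42 members were higher and 0 lower by edgeR, and over all genes tested none passed with edgeR and 17 were higher with DESeq2. Their list score differed by 1.42, with 5 of 6 HFD libraries above all CD libraries (exact permutation test, p = 0.00649; adjusted, 0.0563). Processed pseudogenes can take or lend reads for these genes. Proteasome genes had 26 of 29 members above 0 and a median of 0.85 (camera, adjusted p = 0.000584; adjusted p = 0.611 with an estimated correlation). Adjusted over the list alone, 11 of them were higher and 1 lower by edgeR, against none over all genes tested with edgeR and 5 higher with DESeq2. Psmb2, a subunit of the core particle, had a log2 fold change of 1.90 ± 0.42 and Psma4 of 1.04 ± 0.30, while the lower member, Psmd2 of the regulatory particle (named after its value was seen), had −0.79. The proteasome list score differed by 0.68, with 5 of 6 HFD libraries above all CD libraries (exact permutation test, p = 0.00433; adjusted, 0.0563).

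HFD replicate 3 had the highest score for these 3 lists, and leaving it out lowered the median log2 fold changes to 1.12, 0.97 and 0.48, each still past camera's threshold with the preset correlation (with all libraries, adjusted p = 0.611 with an estimated correlation). Among the 8 libraries with odd counts, 2 HFD and 6 CD, the medians were 3.11, 3.12 and 1.14, where HFD replicate 3 was 1 of the 2 HFD libraries, and the all-even libraries could not be compared among themselves because all of them are HFD. Members of these lists had short transcripts, with a median of 759 nt for OXPHOS and 803.5 nt for ribosomal proteins against 2651.5 nt over the tested genes. With each library's trend with length removed, the median log2 fold changes were 1.28, 0.81 and 0.48, the proteasome list no longer passed (camera, adjusted p = 0.180), and 3 of 6 HFD libraries for OXPHOS and 1 of 6 for ribosomal proteins lay above all CD libraries.

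**Figure D3:**
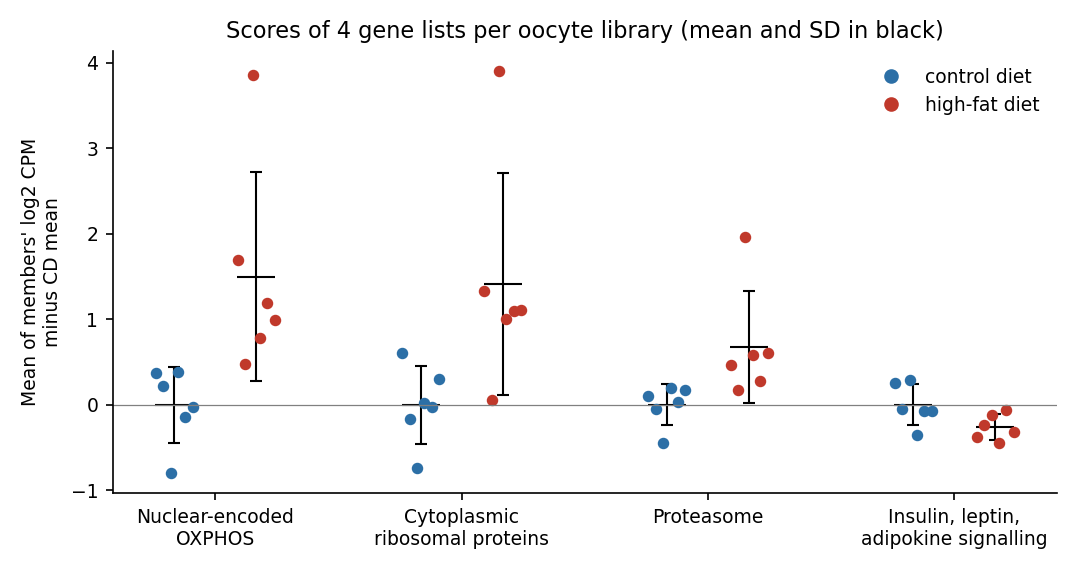
List scores per library (mean over members of log2 CPM minus the mean of the CD libraries) for the lists past camera's threshold, with 1 point per library and the group mean ± SD. HFD replicate 3 has the highest score for OXPHOS (3.86), ribosomal protein (3.90) and proteasome genes (1.96), and for OXPHOS the other 5 HFD libraries also lie above all 6 CD libraries.

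Insulin, leptin and adipokine signalling genes were lower in HFD as a list, with 23 of 31 members below 0 and 8 above, and a median log2 fold change of −0.38 (camera, adjusted p = 0.0251; adjusted p = 0.611 with an estimated correlation). Adjusted over the list alone, 0 members passed by edgeR, as over all genes tested, where DESeq2 called 4 lower. Stat3, the transcription factor downstream of the leptin receptor, stood at 33.4 ± 8.20 CPM in HFD and 74.1 ± 40.6 CPM in CD, a log2 fold change of −1.15 ± 0.33. Prkab1, a regulatory subunit of AMP-activated kinase, had −0.96 ± 0.30. The list score differed by −0.26 (exact permutation test, p = 0.0476; adjusted, 0.206). The call ended without HFD replicate 4 (camera, adjusted p = 0.0571), without CD replicate 1 (0.0874), in the libraries with odd counts (0.288) and with the length correction (0.517). The length-corrected score differed by −0.12, with 0 of 6 HFD libraries above the CD mean (exact permutation test, p = 0.0541; 0.0411 without HFD replicate 3).

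Fold changes followed transcript length across all genes. In the shortest of 5 length classes the median log2 fold change was 0.86, and it was 0.18, −0.15, −0.27 and −0.25 in the following classes. Without HFD replicate 3 the 5 medians were 0.62, 0.083, −0.20, −0.33 and −0.26. Per library, the slope of expression on log2 length was −0.174 ± 0.165 in HFD and 0.174 ± 0.224 in CD (exact permutation test, p = 0.0130). Genes outside the lists matched on length and level, 20 per member, had a median of 1.16 for OXPHOS, against 2.22 in its members, and of 1.26 for ribosomal proteins, against 1.94. The medians are across genes, which are not independent replicates. The share of tallied reads aligned to more than 1 place was also higher in HFD, at 30.3% ± 3.93 against 23.3% ± 2.84 in CD (exact permutation test, p = 0.00216).

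**Figure D4:**
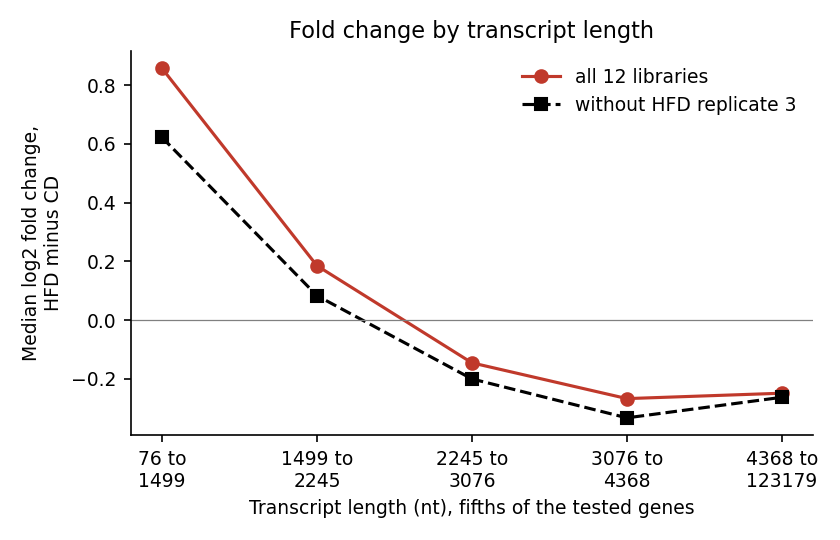
Median log2 fold change, HFD minus CD, of the tested genes in 5 classes of transcript length, from the shortest to the longest, with all libraries and without HFD replicate 3. The median was 0.86 in the shortest and −0.25 in the longest class, and 0.62 and −0.26 without that library.

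The other 22 lists did not pass camera's threshold, and no member passed over all genes tested with edgeR, while DESeq2 called between 1 and 3 members in 13 of them. For 16 of them the sign of the median changed under at least 1 alternative, so no direction is read from them. Camera's direction was opposite in sign to the median for meiotic, TCA cycle, unfolded protein response, inflammation and apoptosis genes, and the mean was opposite to the median for glycolysis, one-carbon, apoptosis and oviduct genes. Maternal-effect and oocyte-identity genes had a median log2 fold change of 0.03 (camera, adjusted p = 0.978), with 5 members higher (Npm2, Khdc3, Zar1l, Zp3 and Dppa3) and 2 lower (Gpr3 and Nlrp4f) adjusted over the list alone, of which Khdc3, Zar1l and Nlrp4f are named after their values were seen. Npm2, a chromatin chaperone of the oocyte, had 1.25 ± 0.34, and Gpr3, a receptor that holds meiotic arrest, −1.35 ± 0.33. Meiotic cell-cycle and spindle genes had a median of 0.05 (camera, adjusted p = 0.978). In that list, Fbxo43, which restrains the anaphase-promoting complex in the egg, had −0.80 ± 0.25 and Wee2, an oocyte kinase, −0.85 ± 0.27. Genes of maternal mRNA decay and translation control had a median of −0.21 (0.234), with gene Ybx2 at 1.74 (1.12 without HFD replicate 3) and gene Pan2 at −0.96 (−0.63 without CD replicate 3). Early zygotic-activation genes had a median of 0.94 over 7 tested members (0.440), of which Tcstv3 at 1.70 passed adjusted over the list alone, and Tfap2c stood at −1.15.

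Metabolic lists outside the respiratory chain gave no call. Medians were 0.61 for mitochondrial biogenesis and dynamics (camera, adjusted p = 0.332; Hspe1 1.18, Esrra 1.26), 0.11 for the TCA cycle and pyruvate metabolism (0.978; Mdh2 3.83, Cs −0.94), and −0.02 for glycolysis and the pentose phosphate pathway (0.870; Slc2a1 −0.59, Ldhb 0.83). They were 0.28 for fatty-acid oxidation (0.713; Etfb 2.77, Hadha 0.90), −0.15 for lipid synthesis, storage and uptake (0.713), and −0.26 for one-carbon, polyamine and amino-acid supply (0.573; Srm 2.53, Tyms 2.30). In the lipid list, Srebf2, the regulator of cholesterol synthesis, had −2.25 ± 0.57 and Fabp5, a fatty-acid binding protein, 1.32 ± 0.35, and both passed adjusted over the list alone. Srebf2 had low counts, at 1.05 ± 0.60 CPM in HFD and 4.99 ± 3.61 CPM in CD. CD replicates 1 and 3 held 7.77 and 11.1 CPM of it, against 2.12 to 3.46 in the other CD libraries, and the diets overlapped. The values of Mdh2, Srm and Tyms rested on HFD replicate 3, without which they were 0.35, 0.23 and 0.14, and that of Etfb was 0.93. The fatty-acid oxidation score was 0.21 higher in HFD, with 5 of 6 HFD libraries above all CD libraries (exact permutation test, p = 0.00866; adjusted over the 26 lists, 0.0563).

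Stress and quality-control lists did not pass either. Antioxidant and oxidative-stress genes had a median of 0.56 (camera, adjusted p = 0.381), with Prdx1 at 0.86 and Gpx1 at 1.12. Genes of the unfolded protein response had 0.01 (0.769), with Ddit3 at 2.82 and Manf at 2.63, which were 1.79 and 1.11 without HFD replicate 3. Heat-shock and immediate-early genes had −0.20 (0.693), and Hsf1, the heat-shock transcription factor, at −1.30 ± 0.36 was lower adjusted over the list alone, while Hsp90aa1 stood at 0.64. Inflammation and interferon genes had 0.12 (0.978), with B2m, the light chain of MHC class I, at 1.36 ± 0.35 higher adjusted over the list alone and Rela at −0.76. Apoptosis and DNA-damage genes had 0.04 (0.769; Mdm2 −1.08, Brca2 −0.53), and autophagy and lysosome genes −0.07 (0.693; gene Lamp2 −1.88, or −1.21 without CD replicate 3, Gabarapl2 0.84).

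Chromatin lists also stayed above the threshold. DNA methylation and genome-defence genes had a median of −0.14 (camera, adjusted p = 0.713), with Dppa3 at 0.99 and Kdm1b at −1.05. Histone-modifying genes had −0.31 with 25 of 34 members below 0 (0.125), with Ezh1 at −1.06 and Kdm6a at −1.12. The values of gene Kdm1b, gene Ezh1 and gene Kdm6a leaned on CD replicate 3, without which they were −0.49, −0.54 and −0.61. Imprinted genes had 0.05 (0.978), with Phlda2 at 1.06 and Airn, which overlaps a gene on the other strand, at 1.21.

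Markers of other cell types that a pool could carry did not separate the diets beyond the spread between pools. Summed cumulus and granulosa markers stood at 888 ± 554 CPM in HFD and 1032 ± 500 CPM in CD (exact permutation test, p = 0.643), with 68.8% of the sum from Serpine2. Without Serpine2 the sums differed by −12.7 CPM (exact permutation test, p = 0.721). The list medians and camera tests here cover only markers that passed the filter. These were 6 of 40 cumulus and granulosa, 6 of 21 oviduct and 7 of 18 stromal, muscle and endothelial markers. As a list the cumulus and granulosa markers had a median log2 fold change of −0.04 (camera, adjusted p = 0.713), in which Scarb1, a lipoprotein receptor, at −0.89 ± 0.28 was lower adjusted over the list alone and gene Fdx1 stood at 0.45 (0.29 without CD replicate 3). Oviduct epithelial markers summed to 72.4 ± 40.9 and 137 ± 143 CPM (p = 0.368 in the exact test; list median 0.14, camera, adjusted p = 0.978; gene Cdh1 −0.65, or −0.079 without CD replicate 3; gene Dnah5 0.50, or −0.042 without HFD replicate 3). CD replicate 1 alone held 384 CPM of that sum, and without it the CD sum was 87.7 ± 86.0 CPM (exact p = 0.768). Cdh1 made up 63.2% of the oviduct sum. Serpine2 and Cdh1 were both lowest in HFD replicates 1 and 2 and CD replicates 2 and 4. There they stood at 63.5 to 125 and 2.22 to 4.06 CPM of total gene counts, so these 2 sums partly follow a split other than diet. Blood and immune markers summed to 54.4 ± 60.3 and 31.5 ± 20.7 CPM (exact p = 0.491; H2-Aa 0.89; gene Cd68 0.34, or 0.11 without HFD replicate 2). HFD replicate 3 alone held 170 CPM of that sum, and without it the HFD sum was 31.32 ± 23.01 CPM and gene H2-Aa 0.069. H2-Aa made up 82.9% of the blood and immune sum. Stromal, muscle and endothelial markers summed to 45.5 ± 6.21 and 83.5 ± 52.2 CPM (exact p = 0.0368; adjusted over the 4 sums, 0.147; list median −0.68, camera, adjusted p = 0.573; Postn −1.16, Pecam1 −1.80). CD replicate 3 held 184 CPM of that sum, and without it the CD sum was 63.4 ± 19.3 CPM (exact p = 0.0649) and gene Pecam1 −0.81.

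On the counts as deposited, the 5 library measures did not differ by diet beyond the spread between pools. The shares of reads aligned to more than 1 place and of reads overlapping no gene did differ (exact permutation test, p = 0.00216 for each). Both are shares of 1 total, so the second can fall because the first rises, and it is not a separate result. So did the slope of expression on transcript length (exact permutation test, p = 0.0130). In exact permutation tests adjusted over 5 measures, total gene counts gave adjusted p = 0.693, genes detected 0.903 (12940 ± 912 in HFD, 12790 ± 275 in CD), genes detected after thinning 0.903 (12883 ± 939 and 12697 ± 244), the share of counts in the 50 highest genes 0.693 (32.2% ± 5.01 and 29.3% ± 2.54), and the cumulus and granulosa sum 0.903. Without HFD replicate 3 the share in the 50 highest genes differed by 4.68 percentage points, against 2.88 with it (exact p = 0.0195, adjusted 0.0974). With the all-even libraries halved, total counts were lower in HFD (−2836580, adjusted exact p = 0.0433). If the tallies of those libraries are doubled, their depth is the halved total, 4954349 to 6896799. That lies below every CD library (8556396 to 10477316), so depth would then differ by diet. Pools of 1 diet were about as far from each other in HFD as in CD, with a root-mean-square log2 distance of 1.11 ± 0.206 against 1.01 ± 0.203 (exact permutation test, p = 0.604).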

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

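The DESeq2 fits of the 100 splits also used for edgeR, the tests on the share of reads aligned to more than 1 place, the list-score tests without HFD replicate 3 and with the length correction, and the length corrections themselves were chosen after the results they bear on had been seen. In 26 of 218 groups of 6 libraries, 1 library stood apart from the other 5 by Dixon's ratio, where chance gives about 10.9. Of these, 15 were HFD replicate 3 and 6 were CD replicate 3. The members of a list share libraries, so the 218 groups are not independent.

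HFD replicate 3 held 14755 detected genes, against 12229 to 12772 in the other HFD libraries, and also 14755 after thinning, as it was the smallest library. Its root-mean-square log2 distance from the other HFD libraries was 1.51. Its list scores were the highest of the HFD libraries for OXPHOS (3.86), ribosomal protein (3.90), proteasome (1.96), early zygotic-activation (1.77), antioxidant (0.93), TCA cycle (0.54) and autophagy and lysosome genes (0.42). Among the named genes that Dixon's ratio set apart, HFD replicate 3 was highest for Mdh2 (7.11 log2 CPM), Srm (5.91) and Tyms (7.99), and lowest for E2f4 (5.601) and Fbxo43 (6.55). Only list scores and genes set apart by this ratio are given here and for the libraries that follow. CD replicate 3 was the highest CD library for Bmp15 (10.88 log2 CPM), Ezh1 (7.12), Kdm1b (9.15), Lamp2 (6.15) and Naa40 (8.31), and the lowest for Fdx1 (6.43). HFD replicate 2 was the lowest HFD library for Nop10 (5.14 log2 CPM) and Ube2s (5.05), and HFD replicate 5 the highest for Kdm1b (7.77). CD replicate 5 was the highest CD library for Postn (4.002), and CD replicate 1 had the lowest score for early zygotic-activation genes (−0.53).

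OXPHOS and ribosomal protein genes were higher in HFD, with medians of 2.22 and 1.94. HFD replicate 3 alone is argued against, since without it the OXPHOS median was 1.12 with 5 of 5 remaining HFD libraries above all CD libraries, and the ribosomal list score still differed (exact permutation test, p = 0.0173), although its median of 0.97 missed the bound of 1 set for it. Uneven recovery of short transcripts stays open for both lists: with the length trend removed the medians were 1.28 (exact p of the score 0.0281) and 0.81 (0.292), and the first, though above the bound of 1 set for it, leaned on HFD replicate 3. With that library left out as well, the medians fell to 0.39 (exact p = 0.0563) and 0.30 (0.548), so replicate 3 together with transcript length cannot be told apart from a change in these transcripts. The diet itself may also contribute and was not tested apart from these.

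The count of genes changed between diets depended on the tool. Of 100 splits of the 12 libraries into 6 and 6, the real one included, 100 reach edgeR's real count of 0 by construction, and the highest called 822, setting HFD replicates 1, 2 and 3 with CD replicates 1, 2 and 4 against the rest, which points to a structure of the samples other than diet. As many as 4 gene lists came from 34 of the 100 (highest other 6), so chance could not be excluded. Few splits, the real one included, reached DESeq2's 769 calls on the filtered genes (3 of 100, highest other 1449, and 1 of 24 in a first draw). Few also reached the 2215 genes at an unadjusted p under 0.05 (4 of 100, highest other 2530) or the 243 genes without overlap (1 of 100, highest other 234). These shares came from sampled splits and were not adjusted over the counts compared. They argue against a random grouping without excluding it. The split that called 822 also gave the 1449 and the 2530. None of these counts separates diet from the structure of the libraries or the all-even counts.

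Reads aligned to more than 1 place, which the gene comparison does not use, made up 30.3% ± 3.93 of tallied reads in HFD and 23.3% ± 2.84 in CD, a difference of 6.94 percentage points with 6 of 6 HFD libraries above all CD libraries (exact permutation test, p = 0.00216, the smallest it can give; adjusted over 3 tallies, 0.00325), while reads overlapping no gene were lower (38.5% ± 1.37 against 41.4% ± 1.30, same p and adjusted p). The tallies are shares of 1 total, so the lower share overlapping no gene can follow from this rise and is not a separate result. For reads aligned to more than 1 place, both HFD libraries with odd counts lay above all CD libraries (2 of 2), which argues against the all-even counts alone as the cause. They were HFD replicate 3 and HFD replicate 5, the latter at 27.5% against 26.5% in the highest CD library. The difference without HFD replicate 3 (exact p = 0.00433) argues against that library alone. That test kept the 4 all-even libraries, so HFD replicate 3 and the all-even counts together were not excluded. The share rose with the OXPHOS score over the 12 libraries (Pearson's r = 0.896, permutation p = 2e-05, adjusted over 2 relations 4e-05; Spearman's rho = 0.937, permutation p = 2e-05), with r = 0.871 without HFD replicates 3 and 1, 0.822 within HFD (exact p = 0.0264) and 0.891 within CD (exact p = 0.0222). With the ribosomal score r was 0.794 (permutation p = 0.0007; rho = 0.769, p = 0.00472), 0.5998 without those libraries, 0.715 within HFD (exact p = 0.0458) and 0.439 within CD (exact p = 0.365). The tally does not say which sequences these reads came from, so short genes with many copies, repeats and ribosomal RNA stay open, as does the diet, which was not tested apart from them.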

How the results depend on the processing

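Added after the data were seen were the tests with halved counts, odd-count libraries, surrogate variables, GC or length correction, the length correction with the block and without HFD replicate 3, and the marker sum without Serpine2; the other alternatives given here, the gene lists and the naming rule were fixed before the data were examined. The edgeR count of 0 genes moved to 470 at an adjusted p of 0.10, 709 with DESeq2, 35 with limma-voom, 456 in the libraries with odd counts (454 higher; HFD replicate 3 is 1 of its 2 HFD libraries), 309 with 1 surrogate variable and 624 with 2, and was 0 under each other alternative, with each library left out included (smallest adjusted p 0.0541 to 0.227, 1491 to 2380 genes at an unadjusted p under 0.05). The cause was not tested. Total counts alone moved the median log2 fold change of all genes from 0.04 to −0.06, and DESeq2 gave 0.17 over its own set of genes.

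With an estimated correlation the medians of 2.22, 1.94, 0.85 and −0.38 are unchanged by construction, while the 4 list calls ended (adjusted p 0.611 for each). Fry, which asks whether members move 1 way and not whether they move relative to other genes, gave an adjusted p of 0.199 for each. The insulin list also lost its call among odd-count libraries (−0.36), with the length correction (−0.21), with block and length (−0.20) and with length and no HFD replicate 3 (−0.22). The proteasome list lost its call in the last 3 (0.48, 0.35 and 0.11), and the ribosomal list in the last (0.30). With each library left out, medians ranged from 1.12 to 2.44 (OXPHOS), 0.97 to 2.17 (ribosomal), 0.48 to 0.96 (proteasome) and −0.41 to −0.30 (insulin), where the call ended without HFD replicate 4 or CD replicate 1, and 3 to 5 lists passed. Histone-modifying genes passed without the filter (−0.34, adjusted p = 0.0424) and without HFD replicate 5 (−0.46, 0.0364).

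The difference in detected genes ranged from −213 (without HFD replicate 3) to 292.5, and after thinning from −188 to 333, with each library left out. Halving the all-even libraries made total counts lower in HFD (−2836580, adjusted exact p = 0.0433), and if their tallies are doubled this is the difference in depth. Other library measures and the spread between pools kept direction and side of the threshold. Among the named genes, 8 changed sign under some alternative. With each library left out, gene Gdf9 ranged from −0.55 to 0.098, gene Bmp15 from −0.59 to 0.025 and gene Dnah5 from −0.042 to 0.77. In the odd-count libraries, Gdf9 was 0.071, gene Cd68 −0.39 and gene Fdx1 −0.17. With 1 surrogate variable Gdf9 was 0.44 and gene Cdh1 0.42, and with 2, Gdf9 was 0.0089, gene H2-Aa −0.038 and gene Srm −0.0038. With the length correction Cd68 was −0.19 and H2-Aa −0.13, with block and length Cd68 was −0.30, and with length and no HFD replicate 3 Cd68 was −0.00054, H2-Aa −0.64 and Srm −0.16.

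Equal replicate numbers did not pair the libraries: same-number correlations exceeded 0.1 for 3 of 6 numbers, and not every library correlated best with its own number. The replicate block gave 0 genes and kept the 4 list calls at the preset correlation, with medians of 1.51, 1.27, 0.69 and −0.37 (without the block, adjusted p = 0.611 with an estimated correlation for each). The planned normalisation without mitochondrially encoded genes was not run, as no such symbol was found in the table as used here. Depth limits genes near the filter. The simulated recovery of 8.96% at 2-fold left out structure shared across libraries, so it does not give edgeR's power in these data.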

Other observations

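The tests on the principal components were chosen after the counts had been seen, and all else here is values. Some maternal transcripts split the pools without regard to diet. In CPM of total gene counts, Gdf9 stood at 551, 558, 559 and 553 in HFD replicates 1 and 2 and CD replicates 2 and 4, and between 3689 and 8233 in the other 8 libraries. Mos, the kinase that holds the egg at metaphase, stood at 8.41, 4.07, 3.96 and 3.74 CPM in the same 4 libraries and between 115 and 1453 CPM in the others. H1foo, the oocyte linker histone, stood at 3167, 2189, 2598 and 1956 CPM there, against 7486 to 20980 CPM elsewhere. Fth1, the ferritin heavy chain, went the other way in these libraries, at 810, 493, 380 and 391.8 CPM, against 9.74 to 341 CPM elsewhere, the highest of these in HFD replicate 3. These genes were singled out after their values were seen, and the 4 libraries are not a group of the study.

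HFD replicate 3 carried more zona pellucida messages than the other libraries, with 1000 CPM of Zp1, 1266 CPM of Zp2 and 4704 CPM of Zp3. It also held 156 CPM of Rpl41, 235 CPM of Rps29 and 311 CPM of Cox17. CD replicate 1 carried 201 CPM of Spp1, 59.4 CPM of Cyp11a1, 11.8 CPM of Sparc and 4.24 CPM of Lyz2, transcripts of epithelial, steroid-forming, stromal and myeloid cells that were near 0 in most other libraries. The first principal component held 35.8% of the variance and did not separate the diets (exact permutation test, p = 0.227). It set HFD replicates 1, 2 and 3 and CD replicates 2 and 4 (−80.1 to −51.7) apart from the other libraries (24.1 to 88.2). These take in the 4 libraries that Gdf9, Mos and H1foo set apart, so that split is not limited to the genes named. The second held 21.9% (exact permutation test, p = 0.0411, not adjusted). On it HFD replicate 3 stood at −119.9, against −29.6 to 31.1 in the other HFD libraries and −7.24 to 58.9 in CD. Plcl1, the gene with the smallest DESeq2 p, had 0.238 CPM in HFD replicate 3 and 0 in the other HFD libraries, against 4.89, 0.890, 12.5, 5.49, 0 and 7.83 CPM in CD replicates 1 to 6.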
